A study of Homo sapiens with 8 samples.

How the data were processed

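RNA was measured in 8 libraries of human microvascular endothelial cells, primary cells that line small blood vessels, at passages 3 to 4. Per the labels' protocols, cells were kept in 2% oxygen at body temperature for 0, 12, 24 or 48 h, with 2 replicates per time. All 8 libraries carry the condition hypoxia in their labels, the 0 h libraries included. Per the labels' protocols, RNA was extracted with phenol-chloroform, reverse transcribed, size selected as cDNA, circularized, linearized and amplified. The study's design text calls the samples biological replicates, but no label says whether they came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be partly technical.

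The deposited data are 1 table per library, which lists 185299 transcripts with a length, an effective length, an estimated count and a TPM, a share of transcripts corrected for length. The estimated counts were deposited by the authors without normalization: 5.8% of the non-zero values are whole at a tolerance of 0, the form that a tool gives when it divides reads between transcripts that share sequence. The TPM values deposited by the authors are those counts divided by effective length and scaled to 1 common total in each library. Per the submitters' processing notes the genome build was hg38. The quantification tool, its version and the transcript annotation are not given in the sources used here. Dividing reads between similar transcripts makes genes with near-identical copies uncertain, so RGPD5, RGPD6, PKD1P1, HIST2H2AA4 and H4C8 are given below as such. How strand was handled is also not given, so a gene and an overlapping or antisense partner cannot be told apart by these counts.

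Transcripts were assigned to genes with the GENCODE 29 annotation of GRCh38 by their identifiers without version. Of the 185299 transcripts, 167622 (90.5%) matched, and all 166890 whose lengths were compared had the same length in both sources. The 17677 unmatched transcripts held 2.16% to 2.41% of each library's counts and stayed out of the tests. The matched transcripts belong to 35031 genes, of which 19900 are protein-coding and 12 are of a long non-coding class, so long non-coding RNAs were largely not analysed here. Estimated counts were summed per gene and rounded to whole numbers. Total estimated counts ran from 26826623 to 34277841 per library, at which 3 counts, the limit that a count of 0 allows, correspond to 0.084 to 0.122 CPM (counts scaled to library size). Reads carry no molecular identifiers, so such limits cover counting error only.

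Gene counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust estimation, TMM factors (0.939 to 1.074) and edgeR's own expression filter, which kept 15639 genes. A single model held all 4 labelled times and all 8 libraries, with 4 residual degrees of freedom, a common biological coefficient of variation of 0.18 and a median of 2.82 prior degrees of freedom. Each later time was compared with 0 h, 24 h with 12 h and 48 h with 24 h, and a joint test asked whether a gene differed between any of the times. A call is a Benjamini-Hochberg adjusted p below 0.05 over the genes tested, two-sided. Levels are CPM on the TMM scale, given as the mean ± SD of the 2 libraries, and fold changes are log2. The standard error of a log2 fold change is its size divided by the square root of F, an approximation.

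The 31 gene lists, with 816 symbols of which 813 matched a gene, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. A measured member of a list is a gene that the expression filter kept. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. P-values were adjusted over the lists of a comparison. Camera with the correlation estimated per list and fry, which asks whether a list's genes move on balance one way without reference to other genes, were alternatives. Named genes are the 6 called genes with the largest change in each direction, among those with a mean of at least 5 CPM and no overlap between the libraries compared, up to 4 members of each list with the smallest p, and a fixed set of hypoxia and endothelial genes named whatever their values. Where no gene was called, the 3 with the smallest p in each direction are named. Members of a list outside this rule are named where they complete a count of calls and were then chosen after their values were seen. Genes on the Y chromosome and the X-inactivation transcripts are not reported by library.

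The alternatives were RLE factors, no filter, a stricter filter, a fit of only the times compared, the replicate number as a block, a test against a 2-fold change, an offset for transcript length, limma on log2(TPM + 1), protein-coding genes alone, DESeq2 1.42.0 and leaving out each library in turn. The test was first tested on simulated data made for the 12 h against 0 h comparison over 15639 genes. It recovered 6% of genes changed 1.5-fold, 50% of those changed 2-fold, 76% of those changed 4-fold and 90% of those changed 8-fold, with 11 false calls. A simulated list of 30 changed genes gave a camera p of 7.1e-73 and an unchanged list a p of 0.17. A single unchanged list cannot show how often camera at its preset correlation calls lists of correlated genes that did not change. Measured lists at 12 h against 0 h had estimated correlations of −0.048 (heat shock) to 0.966 (mitotic). Because the 3 comparisons with 0 h share their control libraries, 20 sets of unchanged groups were simulated to give the overlap expected with no effect. All 8 libraries, those labelled 0 h included, were redrawn around 1 mean per gene.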

Results

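Transcript levels were measured by RNA sequencing in 8 libraries of human microvascular endothelial cells, labelled as 0, 12, 24 and 48 h in 2% oxygen with 2 libraries each. The title gives the subject as these cells under hypoxia, and the times ask which transcripts change as low oxygen continues. Total estimated counts of replicates 1 and 2 were 26826623 and 29724100 at 0 h, and 31715984 and 33916834 at 12 h. They were 30060702 and 28167628 at 24 h, and 34277841 and 31757910 at 48 h. Mitochondrially encoded genes took 4.16% ± 0.092 of counts at 0 h, 4.37% ± 0.007 at 12 h, 4.14% ± 0.042 at 24 h and 4.42% ± 0.028 at 48 h (SD, n = 2). The 10 most abundant genes took 7.75% ± 0.75, 6.61% ± 0.085, 7.73% ± 0.63 and 6.68% ± 0.13 of counts in the same order, but as shares of TPM the order turned, with 9.95% ± 0.46, 10.3% ± 0.007, 10% ± 0.297 and 10.4% ± 0.191. Ribosomal protein genes took 3.66% ± 0.13, 3.64% ± 0.26, 3.61% ± 0.014 and 3.68% ± 0.14.

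The libraries did not resemble each other by labelled time. Across 15639 genes, each of the 8 libraries had its highest Pearson correlation of log2 CPM with a library of another label. The library labelled 0 h replicate 1 was closest to 24 h replicate 1 (r = 0.9887) and 0 h replicate 2 to 24 h replicate 2 (0.991). The library labelled 12 h replicate 1 was closest to 48 h replicate 1 (0.9915), and 12 h replicate 2 to 48 h replicate 2 (0.9919). Libraries of 1 label correlated at 0.9808 to 0.9838, and 821 to 1045 genes lay more than 2-fold apart between them, against 364 to 503 genes between closest libraries. These correlations are across genes, which are not independent replicates. The deposited tables of closest libraries share a number in their names and differ in a letter, which is the same for 0 h and 12 h and another for 24 h and 48 h. What the letters stand for is not given in the sources used here. Every comparison below is therefore between libraries as they are labelled. An n of 2 per label stands for libraries that differed from each other more than from their partners under another label.

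**Figure D1:**
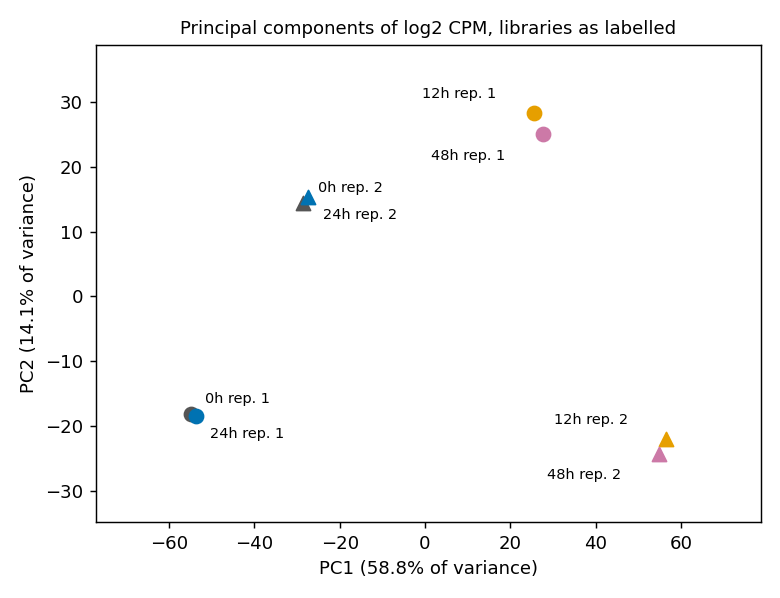
Each point is a library, placed by the first principal component of log2 CPM (horizontal, 58.8% of variance) and the second (vertical, 14.1%), coloured by labelled time, with circles for replicate 1 and triangles for replicate 2. Libraries labelled 0 h and 24 h overlay each other by replicate number at PC1 of −54.89 and −53.74 for replicate 1 and −28.55 and −27.31 for replicate 2, and libraries labelled 12 h and 48 h do so at 25.63 and 27.58 and at 56.36 and 54.92.

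By camera at its preset correlation, lists of the amino acid and endoplasmic reticulum stress responses were higher in the libraries labelled 12 h than in those labelled 0 h, and lists of extracellular matrix, endothelial and lymphatic identity and cell division were lower. None of these list calls held with an estimated correlation after adjustment (smallest adjusted p = 0.211). Of 15639 genes, 1493 were called, 714 higher and 779 lower, and 202 of the higher and 329 of the lower genes differed more than 2-fold. Rankings by size of change, here and below, cover called genes with a mean of at least 5 CPM and no overlap between the libraries compared. The largest increase was in CHPF, a chondroitin polymerizing factor (log2 fold change 3.57, SE 0.84, adjusted p = 0.0465). CHPF went from 0.869 ± 0.033 to 10.35 ± 9.08 CPM, so its libraries labelled 12 h lay far apart. Next were the histone gene HIST2H2AA4 (2.93, uncertain because of a near-identical copy) and the stress-induced transcription factors ATF3 (2.61, SE 0.53) and DDIT3 (2.44, SE 0.37). They were followed by the secreted glycoprotein STC2 (2.34, SE 0.35) and the lipid transporter MFSD2A (2.25, SE 0.18, adjusted p = 0.0129). DDIT3, at 57516588 to 57521737 on chromosome 12 (GRCh38), went from 14.9 ± 6.38 to 80.9 ± 7.36 CPM (SD, n = 2). STC2, at 173314713 to 173329503 on chromosome 5, went from 105.1 ± 39.7 to 531.4 ± 14.7 CPM. In the same ranking, the largest decreases were in GIPC3 (−3.70, SE 0.64), the retinal-oxidizing enzyme ALDH1A1 (−3.30, SE 0.67), LDB2 (−3.13), AEBP1 (−2.60), ART4 (−2.59) and PAPLN (−2.57). ALDH1A1, at 72900662 to 73080442 on chromosome 9, went from 490.2 ± 166.4 to 49.9 ± 36.0 CPM.

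Targets of the hypoxia-inducible factors went both ways. Of the 53 measured members of that list, which shares 17 of its 55 fixed genes with other lists, 6 rose and 4 fell, or 11 and 7 adjusted over the list alone. The list's median log2 change was 0.18 (camera adjusted p = 0.284). Fry, which makes no comparison with other genes, called the list upward (adjusted p = 0.0162), also at 48 h against 0 h (0.0174) and 48 h against 24 h (0.0172), and downward at 24 h against 12 h (0.0166). VEGFA, the endothelial growth factor gene at 43770184 to 43786487 on chromosome 6, rose from 29.3 ± 2.01 to 55.6 ± 12.0 CPM (log2 0.92, SE 0.21, adjusted p = 0.0416). STC2, JMJD6 (0.81), TMEM45A (0.63), HK2 (0.60) and CITED2 also rose, while PLOD1 (−1.08), which modifies collagen lysines, LOXL2 (−1.65), a collagen cross-linking enzyme, WSB1 and FUT11 fell. NDRG1, a gene induced by hypoxia in many cell types, measured 189.6 ± 93.8 at 0 h and 629.1 ± 161.2 CPM at 12 h without passing (log2 1.73, SE 0.47, adjusted p = 0.0633). The other fixed targets did not pass either: BNIP3 at 0.30 (adjusted p = 0.0813), SLC2A1 at 0.23, PGK1 at 0.14, ANKRD37 at 0.36, EGLN3 at 0.28 and ADM at 0.00, with standard errors of 0.09, 0.20, 0.08, 0.27, 0.51 and 0.18. CA9 had 1 count in a library labelled 0 h, 1 in a library labelled 24 h and 0 in the other libraries, below the limit of 3 counts. HIF3A, which encodes an alternative alpha subunit, fell (−1.11, SE 0.21, adjusted p = 0.0302), and HIF1A (−0.21, SE 0.13) and EPAS1 (0.07, SE 0.13) did not pass.

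**Figure D2:**
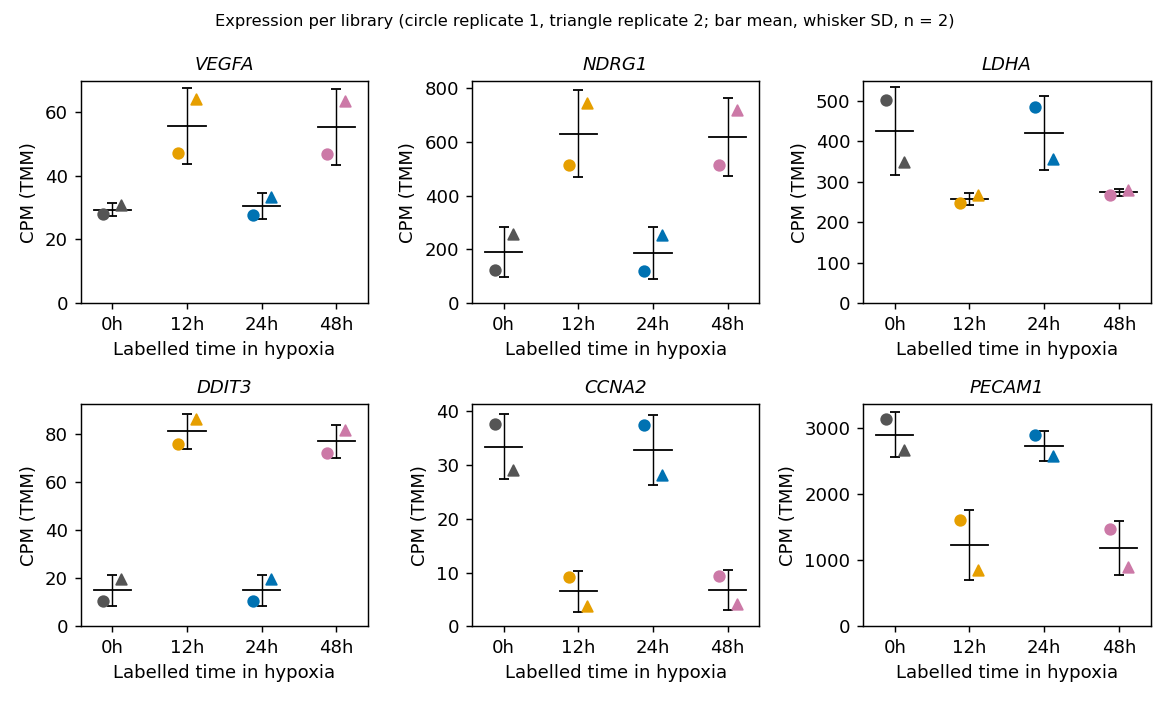
CPM on the TMM scale (vertical, from 0) of 6 genes by labelled time in hypoxia (horizontal, h), with 1 point per library, a bar for the mean and a whisker for the SD of 2 libraries. VEGFA lies at 46.71 to 64.14 CPM in the libraries labelled 12 h and 48 h and at 27.6 to 33.37 CPM in those labelled 0 h and 24 h, and CCNA2 at 3.798 to 9.347 CPM against 28.24 to 37.74 CPM.

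Glycolytic genes did not move together. Of 21 measured, 1 rose and 3 fell, or 2 and 4 adjusted over the list alone, with a median of −0.13 (camera adjusted p = 0.262). The hexokinase HK2 rose, and HK1 (−0.41), the phosphofructokinase PFKM (−0.90) and the aldolase ALDOC (−1.23) fell. LDHA, the lactate dehydrogenase subunit, measured 426.5 ± 108.3 at 0 h and 258.1 ± 14.6 CPM at 12 h (−0.72, SE 0.21, adjusted p = 0.0692). Among 72 nuclear genes of the respiratory chain, UQCRB (−0.43) and ATP5PO (−0.39) fell, and 0 fell when adjusted over the list alone. That list's median was −0.16 (camera adjusted p = 0.0205; adjusted p = 0.636 with an estimated correlation). Its call was lost without 0 h replicate 1 (adjusted p = 0.298) or without 12 h replicate 1 (0.329). None of the 13 mitochondrially encoded genes passed (median −0.04, camera adjusted p = 0.852).

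The integrated stress response list, targets of ATF4, rose. Of 29 members 11 rose and 0 fell, or 21 and 0 adjusted over the list alone. Its median was 0.87 (camera adjusted p = 2.1e-14; adjusted p = 0.457 with an estimated correlation). CEBPB (1.73, SE 0.20), DDIT3, STC2 and the stress sensor SESN2 (1.54, SE 0.25) had the smallest p. Of its 30 fixed genes, 6 also stand in another list, ATF3 and STC2 among them. The unfolded protein list had 6 of 22 members higher and 1 lower, or 11 and 2 adjusted over the list alone (median 0.34, camera adjusted p = 6.0e-05; adjusted p = 0.457 with an estimated correlation). It was led by SYVN1 (1.16), SEC24D (0.71), HERPUD1 (1.54) and DNAJB9 (1.68), which act in protein folding, export and degradation at the endoplasmic reticulum. Immediate early genes were higher in 6 of 17 members and lower in 0, or 10 and 0 adjusted over the list alone (median 0.80, camera adjusted p = 2.4e-07; adjusted p = 0.211 with an estimated correlation). Among them were FOSB (3.05, SE 0.55), ATF3, NR4A2 (2.02, SE 0.41) and ZFP36 (1.15, SE 0.20). Interferon response genes rose in 6 of 37 members and fell in 0, or 21 and 0 adjusted over the list alone (median 1.13, camera adjusted p = 3.4e-12; adjusted p = 0.457 with an estimated correlation). Those that rose included ISG20 (0.91), USP18 (0.91), STAT2 (0.93) and RIGI (0.89). The mean log2 deviation of the interferon list from its 8-library mean was −1.07 and −0.14 in the 2 libraries labelled 0 h and 0.73 and 0.54 in those labelled 12 h.

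Inflammatory NF-kB genes split. Of 26 members, LIF (1.61), PTGS2 (1.4) and CSF3 (1.69), which encode a cytokine, a prostaglandin synthase and a colony-stimulating factor, rose, and the chemokine CX3CL1 (−2.58) fell, or 4 and 2 adjusted over the list alone. The list's median was 0.12 (camera adjusted p = 0.0679), and it passed without 0 h replicate 1 (0.0187) or without 12 h replicate 2 (2.4e-05).

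Some endothelial genes fell. Of 28 identity genes, CLDN5, a tight junction protein gene (1.06, SE 0.25), rose and 5 fell, or 1 and 10 adjusted over the list alone. MMRN1 (−1.69), ENG (−0.91) and TIE1 (−0.64) were among those that fell, and the list's median was −0.70 (camera adjusted p = 7.9e-07; adjusted p = 0.499 with an estimated correlation). PECAM1, at 64319415 to 64413776 on chromosome 17, measured 2895 ± 336.6 at 0 h and 1228 ± 533.5 CPM at 12 h (−1.24, SE 0.34, adjusted p = 0.0633) and did not pass. CDH5 had a log2 change of −0.68 (SE 0.20, adjusted p = 0.0754) and VWF one of −2.45 (SE 1.02, adjusted p = 0.151), also without passing. VWF had 77150 and 66278 counts in the libraries labelled 0 h but 27208 and 4811 in those labelled 12 h. The partners labelled 48 h had 24685 and 3918. Both libraries labelled 12 h thus lay below those labelled 0 h but far from each other. Among 23 genes of angiogenesis and tip cells, the leading cells of a sprout, 0 rose and 5 fell, or 0 and 7 adjusted over the list alone (median −0.76, camera adjusted p = 0.000113; adjusted p = 0.499 with an estimated correlation). The 5 were ESM1 (−1.92), ANGPT2 (−1.94), PDGFB (−1.03), LAMA4 (−0.99) and IGFBP3. In the NOTCH list, JAG2 (−1.32) and LFNG (−2.19) of 13 members fell, or 2 adjusted over the list alone (median −0.62, camera adjusted p = 0.00825; adjusted p = 0.499 with an estimated correlation). The NOTCH call was lost without 12 h replicate 2 (adjusted p = 0.0558). Lymphatic markers fell in 4 of 7 members, or 6 adjusted over the list alone (median −1.08, camera adjusted p = 2.1e-06; adjusted p = 0.211 with an estimated correlation). They included PROX1 (−2.06, SE 0.34), the transcription factor of lymphatic identity, RELN (−1.72), FLT4 (−1.08) and TFF3 (−0.56). The libraries labelled 12 h stood apart from each other: the mean log2 deviation of the identity list was 0.37 in 0 h replicate 2 but −0.074 and −0.751 at 12 h, and that of the angiogenesis list 0.392 but 0.011 and −0.869. In the NOTCH list it was 0.345 but −0.113 and −0.639.

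Matrix genes fell in 11 of 33 members and rose in 0, or 22 and 0 adjusted over the list alone (median −1.03, camera adjusted p = 3.4e-12; adjusted p = 0.457 with an estimated correlation). Their mean log2 deviation was 0.625 and 0.388 in the libraries labelled 0 h but −0.151 and −0.929 in those labelled 12 h. NID1, a basement membrane linker, went from a level of 1374 and 1020 CPM in the libraries labelled 0 h to 487.2 and 389 CPM in those labelled 12 h (−1.45, SE 0.20), and VCAN (−2.05), LAMC1 (−1.12) and LAMB1 (−1.23) fell too. Of 25 matrix remodelling genes, P4HA3 (−2.0), PLOD1 and LOXL2 fell and 0 rose, or 7 and 1 adjusted over the list alone (median −0.32, camera adjusted p = 0.000777; adjusted p = 0.501 with an estimated correlation). Their mean deviation was 0.508 and 0.21 at 0 h but −0.104 and −0.693 at 12 h. Of 22 genes of TGF-beta signalling and endothelial-mesenchymal transition, 5 fell and 0 rose, or 11 and 2 adjusted over the list alone (median −0.45, camera adjusted p = 0.00114; adjusted p = 0.211 with an estimated correlation). The 4 with the smallest p were ID1 (−1.94), BMP4 (−1.31), BMP6 (−0.49) and SMAD6 (−1.42).

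Cell division genes were lower in the list test but few passed singly. Of 32 mitotic genes, CCNA2 (−2.37, SE 0.51), CENPE (−1.80, SE 0.37) and KIF11 (−1.74, SE 0.38) fell and 0 rose, also 3 and 0 adjusted over the list alone. That list's median was −1.99 (camera adjusted p = 4.4e-11; adjusted p = 0.499 with an estimated correlation). The list's mean log2 deviation was 1.33 and 1.03 in the libraries labelled 0 h but −0.15 and −2.25 in those labelled 12 h, a spread within 12 h wider than the distance of 12 h replicate 1 from the 0 h libraries. Of 35 DNA replication genes, POLE2 (−1.04), RRM1 (−0.94), MCM6 (−0.97) and E2F1 (−1.36) fell and 0 rose, or 15 and 0 adjusted over the list alone (median −0.61, camera adjusted p = 2.4e-07; adjusted p = 0.499 with an estimated correlation). Their mean deviation was 0.437 and 0.259 at 0 h but −0.118 and −0.611 at 12 h. Of 77 ribosomal protein genes, RPL10A (−0.41) and RPL3 (−0.60) fell, and 0 adjusted over the list alone (median −0.13, camera adjusted p = 0.0202; adjusted p = 0.673 with an estimated correlation). The ribosomal call was lost without 0 h replicate 1 (adjusted p = 0.275) or without 12 h replicate 1 (0.329).

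Some markers of other cell types passed singly, where 1493 of all 15639 genes tested were called. Of 10 fibroblast markers 7 were measured and COL1A2 (−1.79) and FAP (−1.11) fell, also 2 adjusted over the list alone (median −0.22, camera adjusted p = 0.178). Of the 10, 3 collagens also stand in the matrix list. Of 7 smooth muscle and pericyte markers 0 passed (median −0.79, camera adjusted p = 0.0702). That list passed downward without 0 h replicate 2 (0.0433), 12 h replicate 1 (0.00789), 48 h replicate 1 (0.0472) or 48 h replicate 2 (0.0465), and with the replicate number as a block (0.019). Of 7 epithelial markers KRT10 (0.81) rose, or 2 adjusted over the list alone (median 0.20, camera adjusted p = 0.439). The expression filter kept 4 of 10 leukocyte markers, too few to test, and 0 passed. All 6 erythroid genes were in the deposited tables, but that filter kept 0 of them.

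In all, 18 lists passed camera in the libraries labelled 12 h against 0 h, 7 upward and 11 downward, and 0 passed with an estimated correlation after adjustment (smallest adjusted p = 0.211). The 1493 gene calls depend on the whole series: 0 remained when any 1 of the 4 libraries compared was left out or when only those 4 were fitted, and 774 to 897 when a library of another time was left out. DESeq2 called 2850, limma on TPM 980 and edgeR's test against a 2-fold change 0. The replicate number as a block gave 3187.

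**Figure D3:**
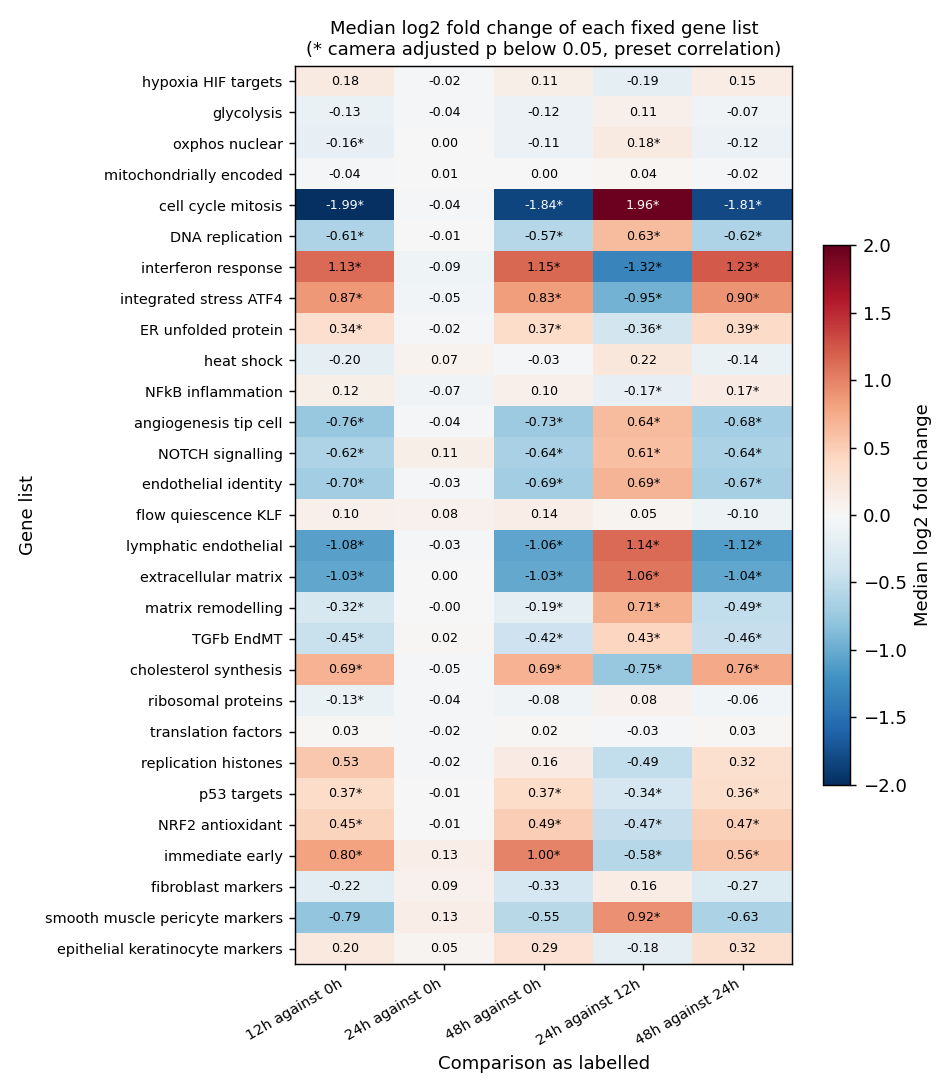
Colour and number give the median log2 fold change of each gene list (rows) in each comparison as labelled (columns), and an asterisk marks a camera adjusted p below 0.05 at the preset correlation. The integrated stress list stands at 0.87 in 12 h against 0 h and the mitotic list at −1.99, and 24 h against 0 h has 0 lists past the threshold.

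Between the libraries labelled 24 h and 0 h no gene and no list passed the threshold. edgeR called 0 genes (smallest adjusted p = 0.537) and 190 had an unadjusted p below 0.05. The genes with the smallest p were RGPD5 (log2 2.51, SE 0.26), TAPBP (2.30, SE 0.38) and PKD1P1 (0.82, SE 0.15) upward and RGPD6 (−0.64, SE 0.11), CDK7 (−0.83, SE 0.18) and CLN8 (−0.76, SE 0.17) downward, none of them past the threshold. Of these, RGPD5, RGPD6 and PKD1P1 share sequence with near-identical copies. DESeq2 called 5 genes, RGPD5, TAPBP, PKD1P1, RGPD6 and NFKBIL1, the last chosen after its values were seen and at 0 counts in both libraries labelled 0 h. edgeR without a filter called RGPD5 alone. The 95% interval of the log2 change reached from −0.44 to 0.55 for VEGFA, −1.12 to 1.06 for NDRG1, −0.51 to 0.47 for LDHA, −0.25 to 0.14 for PGK1 and −0.87 to 0.70 for PECAM1. These intervals come from a fit without pairing and are widened by the difference between replicates, which both times share at NDRG1 (123.3 and 255.9 CPM in replicates 1 and 2 at 0 h, 118.4 and 254.3 CPM at 24 h). Groups that did not overlap made up 20.5% of genes, below the 33.3% that chance gives for interchangeable libraries. These libraries were alike by replicate number and so not interchangeable. The share was 62.1% at 12 h and 63.1% at 48 h against 0 h, 62.3% at 24 h against 12 h and 62.2% at 48 h against 24 h. Of the 29 lists tested 0 passed, the nearest being immediate early genes (median 0.13, camera adjusted p = 0.0732). That list passed with the replicate number as a block (camera adjusted p = 0.0206). It also passed without 0 h replicate 2, 24 h replicate 1, 48 h replicate 1 or 48 h replicate 2. Leaving out 1 of the libraries compared sets 1 replicate number against the mean of both. List calls from such fits therefore mix the replicate difference with labelled time. Without 0 h replicate 1 the interferon, integrated stress, cholesterol and unfolded protein lists passed downward. The respiratory chain, matrix and matrix remodelling lists then passed upward. Without 24 h replicate 2 the same lists except matrix remodelling passed in those directions. Without 0 h replicate 2 the interferon, integrated stress and cholesterol lists passed upward and the ribosomal list downward. Without 24 h replicate 1 the interferon, integrated stress and cholesterol lists passed upward. The mean log2 deviation of the interferon list was −1.067 and −0.141 in replicates 1 and 2 at 0 h. At 24 h it was −1.081 and −0.255, so the direction followed the replicate number left out. The medians of the endothelial identity, lymphatic, matrix remodelling, replication histone, p53 and NRF2 lists lay within 0.03 of 0 and differed in sign from their mean or their test.

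In the libraries labelled 48 h against 0 h, the genes and lists were close to those of 12 h. There were 1381 calls, 682 higher and 699 lower, and 609 genes were higher and 628 lower in both comparisons. CHPF (3.66, SE 0.84), HIST2H2AA4 (3.05, uncertain), ATF3 (2.56, SE 0.52), DDIT3 (2.36, SE 0.37), STC2 (2.36, SE 0.35) and KLF4, a transcription factor of quiescent endothelium (2.24, SE 0.45), rose most. At CHPF the libraries labelled 48 h again lay far apart (10.99 ± 7.58 CPM). GIPC3 (−3.98), ALDH1A1 (−3.33), LDB2 (−3.18), AEBP1 (−2.72), ART4 (−2.70) and PAPLN (−2.61) fell most. VEGFA measured 55.2 ± 11.9 CPM at 48 h (0.91, SE 0.21, adjusted p = 0.0443) and HIF3A 10.3 ± 2.10 CPM (−1.32, SE 0.21, adjusted p = 0.0266). NDRG1 (1.70, adjusted p = 0.0672), BNIP3 (0.33, adjusted p = 0.0706), LDHA (−0.64, adjusted p = 0.0927) and PECAM1 (−1.29, adjusted p = 0.0594) did not pass. Camera passed 16 lists, 7 upward and 9 downward, all 16 with the same direction as at 12 h. They included the integrated stress (median 0.83), interferon (1.15), matrix (−1.03) and mitotic (−1.84) lists by median, and 0 passed with an estimated correlation after adjustment (smallest adjusted p = 0.239). The respiratory chain (camera adjusted p = 0.201) and ribosomal protein (0.121) lists did not pass at 48 h. Both passed without 0 h replicate 2 (0.0255 each), and the ribosomal list also without 48 h replicate 2 (0.0456). The heat shock list had a median of −0.03, a mean of 0.03 and no call (adjusted p = 0.831).

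Both comparisons use the same 0 h libraries, so part of this agreement may come from the shared controls. The 1237 genes shared in direction compare with 66 for independent lists and a mean of 0.15 in 20 simulations of unchanged groups. Unchanged groups give few calls at this threshold, so that mean was set in advance and says nothing of shared controls. At an unadjusted p below 0.01, 1925 genes were shared, against 28.3 in the simulations and 163.6 for independent lists. The simulations held no real difference and no replicate structure, so they do not give the part due to shared controls. The 2 control libraries are too few to split. However, 12 h against 0 h and 48 h against 24 h share no library. Of the 1493 genes called in the former, 1117 were called in the same direction in the latter. Most of the 12 h calls thus recurred without a shared control library. Libraries labelled 0 h and 24 h were closest partners, so the exact part stays unknown. The fold changes at 12 h and 48 h correlated at r = 0.870 with a covariance of 0.532, against 0.519 and 0.094 in the simulations. Called in the same direction at all 3 later times were 0 genes, which the 0 calls at 24 h against 0 h fixed in advance. The mean of 0.05 in the simulations therefore tests nothing. The 1381 calls also fell to 0 without any 1 of the libraries labelled 0 h or 48 h and with only those 4 fitted. They stood at 702 and 719 without 24 h replicate 1 or 2 and at 917 without 12 h replicate 2. They were 2789 with DESeq2, 905 with limma on TPM, 3179 with the replicate number as a block and 0 against a 2-fold change.

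The libraries labelled 24 h differed from those labelled 12 h in 1680 genes, 889 higher and 791 lower. INHBB, an activin and inhibin subunit gene (5.39, SE 1.21, adjusted p = 0.0402), GIPC3 (3.57), ALDH1A1 (3.23), LDB2 (3.12), the retinoic acid receptor RARB (3.06) and LRRC4B (2.98) rose most. ATF3 (−2.82), MFSD2A (−2.45), DDIT3 (−2.43), NIBAN1 (−2.35), STC2 (−2.32) and KLF4 (−2.17) fell most. INHBB stood at 20.91 and 10.07 CPM in the libraries labelled 24 h and at 0.761 CPM and 0 in those labelled 12 h, so its fitted change is imprecise. VEGFA fell (−0.87, SE 0.21, adjusted p = 0.0453) and HIF3A rose (1.05, SE 0.21, adjusted p = 0.0319). Camera passed 19 lists, 11 upward and 8 downward. With an estimated correlation 0 passed after adjustment (smallest adjusted p = 0.270). Smooth muscle and pericyte markers (median 0.92, camera adjusted p = 0.0438; adjusted p = 0.476 with an estimated correlation) passed here with 0 members called. The flow and quiescence list had a median of 0.05 but a mean of −0.12 and no call (adjusted p = 0.547). The smooth muscle call was lost without 12 h replicate 2 (0.184) or 24 h replicate 1 (0.0604). The gene calls fell to 0 without any 1 of the 4 libraries compared and with only those fitted, and stood at 1046 to 1079 without a library of another time. DESeq2 called 2871, the replicate number as a block gave 3310 and edgeR's test against a 2-fold change called 0.

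Between the libraries labelled 48 h and 24 h, 1359 genes were called, 684 higher and 675 lower. ATF3 (2.77, SE 0.53), MFSD2A (2.40), DDIT3 (2.36), STC2 (2.34), HIST2H2AA4 (2.23, uncertain) and KLF4 (2.22) rose most. INHBB (−4.97, SE 1.17), GIPC3 (−3.85), ALDH1A1 (−3.26), LDB2 (−3.17), RARB (−3.07) and PAPLN (−2.69) fell most. VEGFA did not pass (0.86, SE 0.21, adjusted p = 0.0508), nor did NDRG1 (1.73, adjusted p = 0.0654), while HIF3A fell (−1.26, SE 0.21, adjusted p = 0.0275). Of the 1493 genes called between 12 h and 0 h, 1117 were called in the same direction here. Camera passed 17 lists, 8 upward and 9 downward, and 16 of the 18 lists of 12 h against 0 h also passed in the same direction. With an estimated correlation, 0 passed after adjustment (smallest adjusted p = 0.209). Mitochondrially encoded genes (median −0.02, mean 0.01) and the flow and quiescence list (median −0.10, mean 0.14) differed in sign without a call. The calls fell to 0 without any 1 of the 4 libraries compared and with only those fitted, and stood at 805 to 869 without a library of another time. DESeq2 called 2745, the replicate number as a block gave 3131 and edgeR's test against a 2-fold change called 0.

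Over all times, 1417 of 15639 genes (9.1%) differed between any of the 4 labels in edgeR's joint test, and 4507 had an unadjusted p below 0.05. Without a single library the count was 0 (0 h replicate 1, 12 h replicate 2, 24 h replicate 1 or 48 h replicate 2), 15 (48 h replicate 1), 211 (12 h replicate 1), 420 (24 h replicate 2) or 463 (0 h replicate 2). DESeq2 called 3378, limma on TPM 921 and the replicate number as a block gave 2911.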

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

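The tests of whether labels fit the libraries, whether a library was deposited under 2 labels and whether same-numbered replicates share a batch were chosen after the pairing of libraries was seen. The test of a graded series and that of random splits were fixed before their results.

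The changes from 0 h differed between labelled times, which is what drew attention here: edgeR called 1680 genes between the libraries labelled 24 h and 12 h and 1359 between those labelled 48 h and 24 h. The comparison of 24 h with 0 h gave 0 with edgeR, with 190 genes at an unadjusted p below 0.05 and 5 calls by DESeq2.

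All 8 of 8 libraries were closest to a library of another label. The same library deposited under 2 labels is argued against, because the median chi-square per gene between closest libraries was at least 0.73 where sampling noise gives 0.455, over 1899 to 1980 genes whose counts are whole in every library (tolerance 0.001), so that divided reads do not explain the excess. A batch or culture difference that same-numbered replicates carry to every time over most genes is argued against too. The replicate differences correlated at 0.026 at most between times outside the pairs, against at least 0.396 within them. A correlation over all genes cannot exclude such a difference in a part of them, which stays open. Replicate 2 lay above replicate 1 on the first principal component and in the cholesterol list at every label. The interferon list kept no single direction between replicates. Time labels that do not match the libraries would give the count of 8, but that count is the pattern itself and not a separate test, so a mislabelling of samples or tables stays open. Also open and untested is a true return to the start at 24 h with culture differences that change with the state. So is another oxygen level behind the letter in the tables' names. The labels' treatment text seems to lack a word before it names 2% oxygen. Partner libraries that differ in that letter had a median absolute log2 difference of 0.081 to 0.101, against 0.2 to 0.208 within a label. These values argue against a broad effect of the letter on most genes.

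Across 15639 genes, the difference between the replicates labelled 24 h correlated with the 12 h minus 0 h difference, with which it shares no library, at r = 0.325 (genes are not independent), and 65.3% of genes had the same sign. The replicate difference at 0 h correlated with the 48 h minus 24 h difference at 0.317. Replicates that are successive states of 1 graded series would give such values. Over all genes a single direction is not shown: the replicate differences at 0 h and 24 h were unrelated to those at 12 h and 48 h (−0.053 to 0.026). On the first principal component, however, replicate 2 lay above replicate 1 at every label. On the second, replicate 2 lay above replicate 1 at 0 h (14.43 and −18.14) and below it at 12 h (−22.01 and 28.31). Successive states need not change the same genes, so these values do not decide. The inflammatory list did not rise or fall steadily, which successive states need not do either. Its mean log2 deviation was 0.14 and −0.06 in the libraries labelled 0 h and 0.53 and −0.54 in those labelled 12 h. That the replicates were cultures of unlike density, passage number or donor was not tested and stays open.

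The joint count of 1417 genes was set against 100 splits of the 8 libraries into 4 pairs, drawn from 105. With the labelled split included, 8 called at least as many genes, and the highest other split called 11028. Of these 8 splits, 7 pair libraries only within 0 h and 24 h and within 12 h and 48 h. They keep the contrast between those times, so the count does not decide on chance. Splits that keep the closest pairs of 0 h and 24 h alone or of 12 h and 48 h alone called 5198 to 6073 genes. Keeping no closest pair, those that exchange libraries between 0 h and 24 h, between 12 h and 48 h or both called 1222, 1483 and 1286. Within those times the labelled split, at 1417, thus stood among the exchanged ones. The highest split puts together the libraries that share a number in the names of the deposited tables. These are the closest pairs already given, so its count follows from their closeness. The names do not rest on expression, so their match with these pairs is separate evidence. The number follows expression more closely than the labelled time does, but what number and letter stand for stays open. No biological comparison was made on this highest split.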

How the results depend on the processing

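RLE factors, a stricter filter, protein-coding genes alone and an offset for transcript length kept every count of called genes within 1.5 times its value, as did no filter except at 24 h against 0 h, where it called 1 gene. In the order 12 h against 0 h, 48 h against 0 h, 24 h against 12 h and 48 h against 24 h, fitting only the times compared and testing against a 2-fold change gave 0 calls each, and DESeq2 gave 2850, 2789, 2871 and 2745, with 5 at 24 h against 0 h and 3378 over any time. limma on log2(TPM + 1) gave 980 at 12 h against 0 h, 905 at 48 h against 0 h and 921 over any time. Leaving out 1 library gave 0 to 897, 0 to 956, 0 to 1079 and 0 to 869 calls in that order and 0 to 463 over any time, where a lone library is assumed to vary like the other groups. The replicate number as a block gave 3187, 3179, 3310 and 3131 calls in that order, 2911 over any time and 0 at 24 h against 0 h. With 2 numbers only, they do not establish a pairing: the replicate differences correlated at 0.396 between 0 h and 24 h and at 0.554 between 12 h and 48 h, and at −0.053 to 0.026 between the other times. Lists passing with an estimated correlation were 0 in each of these 4 comparisons, and fry gave 6, 7, 8 and 7. At 24 h against 0 h leaving out 1 library gave 0 to 7 lists and the block 1 list, immediate early genes (camera adjusted p = 0.0206). With the block the smooth muscle and pericyte list passed downward at 12 h against 0 h (0.019) and 48 h against 24 h (0.0303), and the inflammatory list lost its call at 24 h against 12 h (0.0792) and 48 h against 24 h (0.129). At 24 h against 0 h the interferon list turned upward without 0 h replicate 2 (adjusted p = 2.5e-06) or 24 h replicate 1 (0.00016), as did the integrated stress list (5.9e-07 and 1.6e-06) and the cholesterol list (1.1e-06 and 2.3e-06), and each was downward with a call without 0 h replicate 1 (7.2e-14, 4.5e-10 and 2.4e-10) or 24 h replicate 2 (4.1e-10, 2.7e-08 and 1.8e-09). Their highest values, without 12 h replicate 1, were 0.541, 0.942 and 0.769. The inflammatory list at 24 h against 12 h turned upward without 12 h replicate 1 (0.989), and its lowest value was 3.5e-06 without 12 h replicate 2. Genes called in the same direction at all 3 later times were 8 at an unadjusted p below 0.01, against 11.8 in simulations and 0.2 for independent lists. As shares of TPM, which divide by length, mitochondrial genes took 9.99%, 10.2%, 10.1% and 10.3% at 0, 12, 24 and 48 h, ribosomal protein genes 12.3%, 12.0%, 12.2% and 12.1%, the 10 most abundant genes 9.95%, 10.3%, 10% and 10.4% and the 50 most abundant 23.6%, 23.0%, 23.6% and 23.2%. Of the values of single named genes under the alternatives, 9772 kept their side of the threshold, 2543 lost a call and 234 gained one. With a call in either fit, 0 reversed. A value that changed direction without a call in either fit counts as kept. Of those of single lists, 1401 kept their side of the threshold, 140 lost a call, 47 gained one and 7 reversed with a call in either fit. Among the kept, the lymphatic and replication histone lists turned downward at 24 h against 0 h with the block, without a call. In simulation the test recovered 50% of genes changed 2-fold at 12 h against 0 h, so smaller changes can be missed at these depths and this number of libraries.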

Other observations

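Further stress and growth-arrest genes moved in the libraries labelled 12 h against 0 h. Of 22 p53 targets 8 rose and 1 fell, or 9 and 2 adjusted over the list alone (median 0.37, camera adjusted p = 0.0038; adjusted p = 0.211 with an estimated correlation), with SESN2 (1.54), CDKN1A, the cell cycle inhibitor p21 (0.72), MDM2 (0.52) and GDF15 (0.73) at the smallest p. CDKN1A stood at 355.1 and 422.6 CPM in the libraries labelled 0 h and at 639.3 and 643.9 CPM in those labelled 12 h. Of 18 antioxidant targets of NRF2 5 rose and 0 fell, or 9 and 1 adjusted over the list alone (median 0.45, camera adjusted p = 0.00104; adjusted p = 0.211 with an estimated correlation), led by SRXN1 (0.64), the cystine transporter SLC7A11 (1.31), SQSTM1 (0.90) and the ferritin light chain FTL (0.89). None of 23 cholesterol synthesis genes passed singly, although the list was higher (median 0.69, camera adjusted p = 0.00242; adjusted p = 0.599 with an estimated correlation), a call lost without 0 h replicate 1 (adjusted p = 0.244).

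In the flow and quiescence list KLF4 (2.19) and ASS1 (1.05) of 11 members rose, or 3 with 2 lower adjusted over the list alone, without a list call (median 0.10, camera adjusted p = 0.403). Heat shock genes had 0 of 14 past the threshold (median −0.20, camera adjusted p = 0.666). Of 33 translation factors EIF6 (0.54) rose and EIF3E (−0.71) fell, also 1 and 1 adjusted over the list alone (median 0.03, camera adjusted p = 0.860). Of 13 replication histones measured H4C8 (1.16, uncertain among near-identical copies) rose, or 2 adjusted over the list alone (median 0.53, camera adjusted p = 0.0702), and the list passed without 12 h replicate 2 (0.021).

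The lists differed in how the 8 libraries were ordered. The mean log2 deviation of the cholesterol list was −0.88 and 0.15 in the libraries labelled 0 h, 0.16 and 0.60 in those labelled 12 h, −0.91 and 0.10 at 24 h and 0.13 and 0.65 at 48 h. The NRF2 list, by contrast, stood at −0.23 and −0.21, 0.12 and 0.28, −0.23 and −0.21, and 0.17 and 0.31, and the inflammatory list at 0.14 and −0.06, 0.53 and −0.54, 0.05 and −0.08, and 0.44 and −0.49. These values are given per library with no explanation.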
